A study of Mus musculus with 2 samples.

How the data were processed

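Gene expression was measured with biotin-labelled RNA on Affymetrix mouse arrays in 2 cultures of mouse embryonic fibroblasts (MEFs), 1 carrying both normal copies of Fut8 (Fut8+/+) and 1 homozygous for the disrupted gene (Fut8-/-). Each genotype is represented by 1 array here. The series' design text speaks of 3 cultures per genotype; per the labels each array is a single replicate, and whether its RNA came from 1 dish or several is not given in the sources used here. Genotypes were taken from the genotype label of each array.

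The values analysed were the authors' deposited signal intensity values, 1 per probe set and array, on a linear scale. Per the submitters' processing notes they were made with GCOS, the Affymetrix GeneChip Operating Software. Its version, the signal algorithm, the scaling target and any detection calls are not given in the sources used here. The deposited table held 45101 probe sets, with a median signal of 20.5 on the Fut8+/+ array and 16.9 on the Fut8-/- array. The means after trimming 2% from each end were 189 and 164, so the 2 columns had not been brought to a common trimmed mean over all probe sets. Scale and centring of the deposited values therefore stay unknown beyond their being linear.

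Signals were put on the log2 scale, and the log2 ratio of Fut8-/- over Fut8+/+ was centred on its median over probe sets above the 40th percentile on both arrays. This median was -0.22, which multiplies the Fut8-/- signals by 1.16. Scaled signals below the 40th percentile of both arrays pooled (a signal of 12.3) were then raised to that floor. A ratio with one array at the floor is a lower bound and is given as at least that many fold. A gene was counted as measured where the brighter array reached the 60th percentile, a signal of 39.1. Measured genes with a floored ratio of 2-fold or more were counted as higher or lower. Signals are printed as deposited, while ratios and folds are centred and floored.

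Probe sets were named from the platform annotation, in which 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none; 64 were controls. Only those with 1 symbol were used for genes. Their gene identifiers matched the gene table of assembly GRCm38.p6 for 34741 probe sets, which changed 0 symbols. That table also gave each gene's chromosome; coordinates from it are not printed, because the arrays' files name no genome build. For a gene with several probe sets the one with the highest mean log2 signal was taken, which gave 18193 genes, 10164 of them measured. Probe sets of one gene that lay above the floor on both arrays differed in ratio with an SD of 0.40 on the log2 scale, or 1.32-fold (5389 genes). This spread is technical, within this pair of arrays, and no estimate of the error between cultures.

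With 1 array per genotype no test of genotype can be made, and no p-value is given; the number of arrays limits the precision of every value. Genes were counted by the fixed fold above. Of 27 gene lists, 25 had at least 5 measured members; for each of these the median log2 ratio was set against the medians of 10000 random lists of as many measured genes, matched on mean log2 signal in 20 bins. A list was called outside where its median left the central 95% of these. This describes the 2 arrays only. The lists held 677 members, 38 of which had no probe set of their own name here. The lists, the fold, the floor, the filter and 9 alternative settings were chosen before the data were examined. Named genes were Fut8, the 12 genes with the largest floored ratio in each direction whose probe sets above the floor all had the same sign (clone and predicted names passed over), up to 4 members of each list with the largest absolute ratio, and Egfr, Tgfbr1, Tgfbr2, Lrp1, Itga3, Mmp9, Mmp12, Mmp13 and Eln, chosen in advance from published work on Fut8. Other genes named in the text were chosen after their values were seen.

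The steps were tested on a simulated pair of arrays, built from each probe set's mean log2 signal over both real arrays. In it 200 of 18193 genes were changed 4-fold. Noise was drawn from how far probe sets lay from their gene's median ratio, by signal level. For genes with few probe sets such deviations understate the spread, so the counts below may be too favourable. The changed genes were drawn only from measured genes whose mean signal lay above the measured limit, and variation between cultures was not simulated. Of the changed genes, 193 were recovered, and 370 of the 17993 unchanged genes passed the 2-fold limit. The unchanged genes include those too dim to be called, so the share among measured genes is larger. Unchanged genes passing it numbered 53 with the brighter array at or above the 75th percentile and 8 at the 90th. A simulated shift of -0.3 was estimated as -0.296, and 9 of 200 random lists of 20 genes fell outside the central 95%.

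The alternatives were no centring, quantile normalization, loess of the ratio on the mean signal (span 0.4), a floor at the 20th or 60th percentile, a pseudocount of 16 in place of the floor, the median over all probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at, and no filter on the brighter array. A further 4 were chosen after seeing the data: a filter at the 75th or the 90th percentile, each chromosome centred on its own median, and genes of chromosomes 7, 12, 13, X and Y left out. The grouping of genes by chromosome and 4 further gene lists were also chosen after seeing the data. All columns of signal in the deposited table were used. Detection calls and scanner files were not used here. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.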

Results

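Messenger RNA levels were compared between 2 cultures of mouse embryonic fibroblasts, cells grown from the connective tissue of embryos, that differed in Fut8. Fut8 encodes the alpha1,6-fucosyltransferase that adds the core fucose to N-glycans. There was 1 Fut8+/+ array and 1 Fut8-/- array, so none of the differences below has a replicate check. The comparison asks which transcripts differ in level between the 2 genotypes. Across the 23889 probe sets above the floor on both arrays, the log2 signals of the arrays had a Pearson correlation of 0.955 and a Spearman rank correlation of 0.945; these are across probe sets, which are not independent replicates. Spiked hybridisation controls, which carry no culture RNA, had a median log2 ratio of -0.06 as deposited and 0.16 after centring on the arrays' genes (18 probe sets, SD 0.081). Ratios of 3-prime to 5-prime signal, a sign of RNA integrity, were 0.812 for Gapdh and 1.20 for beta-actin on the Fut8+/+ array, and 0.732 and 1.25 on the Fut8-/- array.

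Fut8 itself was 14.1-fold lower on the Fut8-/- array at the brightest of its 3 probe sets, with a signal of 190.9 against 11.7, the latter just above the floor of 12.3 once scaled. The other 2 probe sets of the gene were below the floor on both arrays, with signals of 2.55 and 7.68 in 1 case and 8.34 and 0.845 in the other, and give no ratio. The gene lies on chromosome 12 of assembly GRCm38.p6. Whether these probe sets lie in the deleted part of the gene is not given in the sources used here, so the lower signal bears on the genotype label only if the brightest probe set reads that part. The Fut8 level depends on the floor: the log2 ratio was -3.81, and -2.29 with a floor at the 60th percentile.

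The Fut8-/- culture had lower signals for extracellular matrix genes as a group. Lox, the lysyl oxidase that cross-links collagen and elastin, was at least 237-fold lower, with signals of 2929 and 4.09. Interferon-induced genes and stress genes of the unfolded protein response were also lower as groups, whereas enzymes of cholesterol synthesis and the Hox and limb position genes were higher as groups. Of 10164 measured genes, 618 (6.08%) were at least 2-fold higher in Fut8-/-, 860 (8.46%) were at least 2-fold lower and 8686 lay between. Without centring, which lowers log2 ratios measured above the floor on both arrays by 0.22 and those with one array at the floor by less, the counts were 416 and 1205, so that higher genes made up 25.7% of those counted in place of 41.8%. At least 4-fold differences numbered 171 higher and 278 lower, and at least 16-fold differences 25 and 41. Of the higher genes 102 were at the floor on the Fut8+/+ array, and of the lower genes 154 were at the floor on the Fut8-/- array. Among genes with more than 1 probe set above the floor, all probe sets had the same sign for 277 of 325 higher genes and 343 of 419 lower ones.

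The named higher genes include Cd24a, which encodes a small glycosylphosphatidylinositol-anchored surface glycoprotein. Its signal was 21.1 in Fut8+/+ and 6025 in Fut8-/-, a 332-fold difference. Ratios with one array at the floor are lower bounds and have no order among themselves or against Cd24a. Such bounds were found for the Y-linked translation factor gene Eif2s3y (at least 268-fold), the ribosomal protein gene Rpl39l (at least 259-fold), Pcbd1 (at least 136-fold) and the matrix protein gene Postn (at least 92.8-fold, from 11.3 to 984). Pdgfrl was at least 63.6-fold higher, the Y-linked demethylase gene Kdm5d at least 61.7-fold, the RNA-binding protein gene Bicc1 55.0-fold, the microsomal glutathione transferase gene Mgst1 45.5-fold, the Y-linked Uty at least 38.9-fold, Erdr1 35.1-fold and the transcriptional regulator gene Eya4 at least 29.9-fold. On the other side, Arhgdib was at least 238-fold lower, and the fibulin family gene Efemp1 at least 236-fold lower. The X-linked homeobox gene Rhox5 was 171-fold lower, with signals of 6773 and 34.0. Lower signals were also measured for the heparan sulfate 6-O-sulfotransferase gene Hs6st2 (at least 101-fold), the growth factor gene Ptn (89.1-fold), the NADPH oxidase subunit gene Cyba (at least 64.8-fold), Serpinf1 (63.7-fold), which encodes pigment epithelium-derived factor, and the X-inactivation transcript Xist (37.2-fold, from 656 to 15.2).

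**Figure D1:**
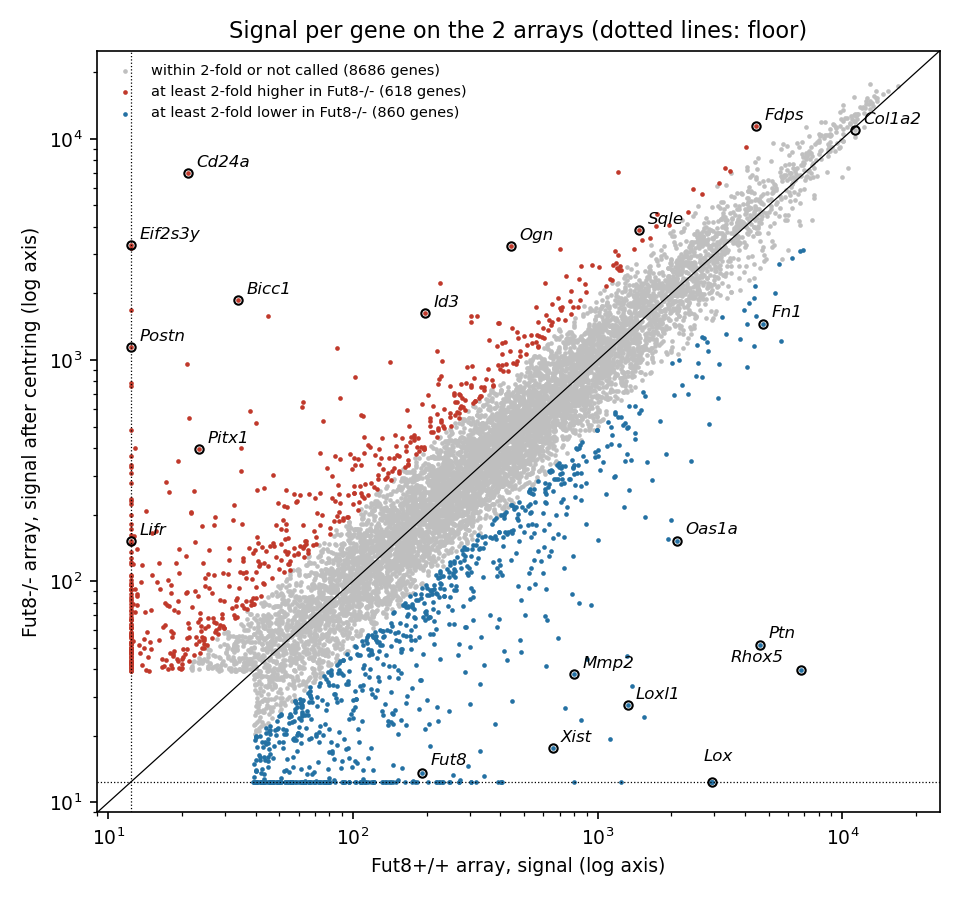
Each point is 1 of 10164 measured genes, with its Fut8+/+ signal on the x axis and its centred Fut8-/- signal on the y axis, both on log axes in array signal units; dotted lines mark the floor of 12.3 and the diagonal marks equal signals. Red points are the 618 genes at least 2-fold higher in Fut8-/-, blue points the 860 at least 2-fold lower, and Cd24a (332-fold higher) and Lox (at least 237-fold lower) lie far from the diagonal.

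Genes of the extracellular matrix were lower in Fut8-/- as a group. Of 32 measured members, 14 were at least 2-fold lower, 2 were at least 2-fold higher and 16 lay between, and the median log2 ratio of -0.79 was below the medians of all 10000 random lists. Fibulin-5 (Fbln5), an organiser of elastic fibres, was 58.2-fold lower with signals of 1126 and 16.6. The lysyl oxidase-like gene Loxl1 was 48.3-fold lower and the basement membrane gene Nid1 41.3-fold lower. The 2 higher members were Postn and the collagen gene Col18a1 (2.01). The abundant collagen gene Col1a2 had a log2 ratio of -0.04 and Sparc -0.10, so the lower signals were uneven across the list. Among 17 metalloproteinases and their inhibitors, 4 were at least 2-fold lower and 0 at least 2-fold higher (median -0.52, percentile 0.44). Without centring 7 were lower. The 4 were the gelatinase gene Mmp2, with signals of 799 and 32.7 (log2 ratio -4.39), Mmp23 (at least 13.2-fold), Adam19 (at least 9.02-fold) and Adam12 (5.87-fold). This list was inside the range of random lists (median -0.30) once genes of chromosomes 7, 12, 13, X and Y were left out. Mmp9, Mmp12, Mmp13 and the elastin gene Eln were below the measured range on both arrays.

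Markers of the fibroblast itself were lower as a group, as the matrix genes were, whereas markers of other cells differed from list to list. Among 11 fibroblast markers measured of 15 on the array, 4 were at least 2-fold lower, led by the homeobox gene Prrx1 (at least 17.9-fold) and Fbln2 (5.06-fold). The receptor gene Pdgfrb was the 1 at least 2-fold higher (0 without centring). Dcn, Lum, Thy1 and Fap were below the measured limit on both arrays. The list median of -0.65 was below those of all random lists, and the list shares genes with the matrix list. Smooth muscle and myofibroblast genes were mixed, with 3 of 10 at least 2-fold lower (Myl9, Tagln and Des) and Mylk 4.04-fold higher; their median of -0.32 was inside the random range. Of 5 epithelial and keratinocyte markers measured among 23 on the array, 4 were at least 2-fold higher, among them keratin 19 (Krt19, at least 14.6-fold) and desmoplakin (Dsp, at least 6.70-fold), while Epcam was 2.43-fold lower (median 2.74, percentile 99.9). Integrins, cadherins and other adhesion genes gave 6 lower and 2 higher of 16 (median -0.50, percentile 1.12). Itga6 (5.13-fold), Vcam1 (3.90-fold) and Itgb8 (3.42-fold) were lower and P-cadherin (Cdh3) at least 3.85-fold higher. The adhesion list was inside the random range with a floor at the 60th percentile (median -0.30), without a filter on the brighter array (median 0) and under 3 more settings.

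Of the other enzymes of fucose metabolism, all 12 measured members of the fucosylation and GDP-fucose list lay within 2-fold (median -0.24, percentile 11.6; outside, at -0.44, with the filter at the 75th percentile). The largest difference was that of the fucosidase gene Fuca2 (-0.98); without centring the Fuca2 log2 ratio was -1.20, more than 2-fold lower. In the N-glycan processing list 17 of 20 genes lay within 2-fold (median -0.23, percentile 8.55). The mannosidase gene Man2a1 was 3.72-fold lower and Mgat5, which starts a branch of complex N-glycans, 3.28-fold lower, while Mgat3, which adds the bisecting N-acetylglucosamine, was 2.61-fold higher. Receptors known as carriers of core fucose were within 2-fold after centring, whereas the Egfr log2 ratio without centring was -1.02. Centred, the log2 ratio was -0.80 for Egfr, -0.63 for Tgfbr1, -0.60 for Tgfbr2, -0.34 for Lrp1 and -0.22 for the integrin gene Itga3, and the probe sets of Tgfbr2 and of Itga3 differed in sign. Of 24 growth factor receptors 5 were at least 2-fold higher, among them the leukaemia inhibitory factor receptor gene Lifr (at least 12.3-fold) and Osmr (3.26-fold), and 3 at least 2-fold lower, among them Mertk (at least 3.44-fold). The median of this list was -0.22 (percentile 9.08).

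Genes of the TGF-beta family and its targets moved both ways. Of 27 measured, 5 were at least 2-fold higher and 4 at least 2-fold lower. The target genes Id3 (8.30-fold, from 196 to 1401), Tgfbi (6.92-fold) and Smad6 (6.43-fold), an inhibitor of the pathway, were higher. The latent TGF-beta binding protein gene Ltbp2 was at least 5.81-fold lower and the matricellular gene Ccn2 4.36-fold lower. The list median was -0.31 (percentile 0.69) and its mean 0.03, of the other sign. The median was inside the random range when each chromosome was centred (-0.21), when the median over all probe sets was used (0) and with the filter at the 90th percentile (-0.21).

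Interferon-induced genes were lower in Fut8-/-. Of 27 measured, 13 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.90 that was below all random lists. The 2-5A synthetase gene Oas1a was 13.9-fold lower (2115 and 131), the immunoproteasome subunit gene Psmb8 10.5-fold, Oas2 at least 8.67-fold and the regulator gene Irf7 7.14-fold lower. Chemokines and cytokines gave 5 lower and 3 higher of 15 (median -0.37, percentile 2.31; 6 lower and 2 higher without centring), with Cxcl12 3.92-fold and Ccl5 3.09-fold lower and Ccl9 5.83-fold higher. That list was inside the random range without centring (percentile 2.91) and under 4 more settings. None of 5 macrophage and leukocyte markers differed by 2-fold (median -0.24, percentile 40.1), and the 2 measured endothelial markers, Egfl7 and Eng, had log2 ratios of -0.55 and 0.47. Without centring a further endothelial marker was measured, and this gene, Plvap, was at least 2-fold lower.

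Genes of the unfolded protein response and of amino acid stress were lower, 9 of 24 by at least 2-fold and 0 higher by that much (median -0.59, below all random lists). Trib3 was 4.43-fold lower, Chac1 3.93-fold and the phosphatase subunit gene Ppp1r15a 3.37-fold; Ddit3, which encodes CHOP, was 4.19-fold lower, although its probe sets differed in sign. The chaperone gene Hspa5, also on the list, had a log2 ratio of -0.11. Genes of cholesterol synthesis were higher. Of 20 measured, 4 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.65 above all random lists. Pmvk (2.84-fold), Idi1 (2.65-fold), squalene epoxidase (Sqle, 2.62-fold, from 1476 to 3329) and farnesyl diphosphate synthase (Fdps, 2.56-fold) led it.

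Proliferation genes lay close together on both arrays. Among 35 mitotic genes only the cyclin gene Ccnb2 passed 2-fold (2.30-fold higher), 0 did so without centring, and the median of 0.13 (-0.09 without centring) was inside the random range. It was outside when each chromosome was centred on its own median (percentile 99.78) and without chromosomes 7, 12, 13, X and Y (0.31). The p53 and senescence list was also inside (18 genes, 2 higher, 1 lower, median -0.03 and 0.14 after quantile normalization), with Ephx1 2.49-fold higher and Sesn2 2.18-fold lower. Glycolysis and hypoxia genes gave 4 lower and 1 higher of 21 (5 and 0 without centring; median -0.13, percentile 6.09), the prolyl hydroxylase gene Egln3 being 6.07-fold lower and the vascular growth factor gene Vegfa 2.53-fold lower. In the Wnt list 3 of 13 were at least 2-fold lower, Wnt10a by 4.70-fold, and 2 were at least 2-fold higher, Ccn5 by 7.13-fold; without centring 6 of 14 were lower and 1 higher. Its median of -0.52 (percentile 1.72) was inside the random range under 6 of the 12 other settings, for example after centring each chromosome (-0.33). Of 6 adipocyte markers 1, Pparg, was at least 2-fold lower (2.60-fold; list median -0.22, percentile 11.7).

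Transcription factors that mark position along the limb and trunk differed in both directions. Of 32 measured Hox and limb genes 13 were at least 2-fold higher, 5 at least 2-fold lower and 14 between, and the median of 0.69 was above all random lists. The hindlimb factor gene Pitx1 was 16.9-fold higher (23.4 and 340), Tbx18 11.4-fold and Hoxd8 7.51-fold, whereas Hoxb2 was at least 22.0-fold lower. Chondrocyte and bone markers were higher for 3 of 5 (median 1.77, percentile 99.96), among them osteoglycin (Ogn, 7.38-fold, 443 and 2810) and Omd (3.93-fold), with Sox5 at least 3.39-fold lower (2 lower without centring). The log2 ratio of Sox9 was -0.93. These 5 were the measured ones among 19 on the array, and Col2a1, Acan and Sp7 were not measured. Skeletal muscle markers were higher for 3 of 5, led by Pax3 at 8.65-fold (median 1.18, percentile 98.2), but for only 1 of 5 without centring, and the median was inside the random range with a floor at the 60th percentile (0.41). The probe sets of Ckm, 1 of the 3, differed in sign. Only 5 of 24 on the array were measured, and Myod1, Myog and Pax7 were not among them. Neural and glial markers gave 4 lower and 1 higher of 7 measured among 18 on the array (median -1.39, percentile 0.595), with Sox2 at least 9.60-fold and nestin (Nes) 4.77-fold lower. The medians of the epithelial, chondrocyte, skeletal muscle and neural lists were inside the random range without a filter on the brighter array (0 for each). Imprinted growth genes gave 3 higher, Sgce (at least 26.4-fold), Plagl1 (4.16-fold) and Igf2r (2.78-fold), and 2 lower, of which the cell cycle inhibitor gene Cdkn1c was 19.4-fold lower. Their median of 1.47 (percentile 99.8) turned to -1.68 without centring, where 7 were measured, 3 higher and 4 lower.

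**Figure D2:**
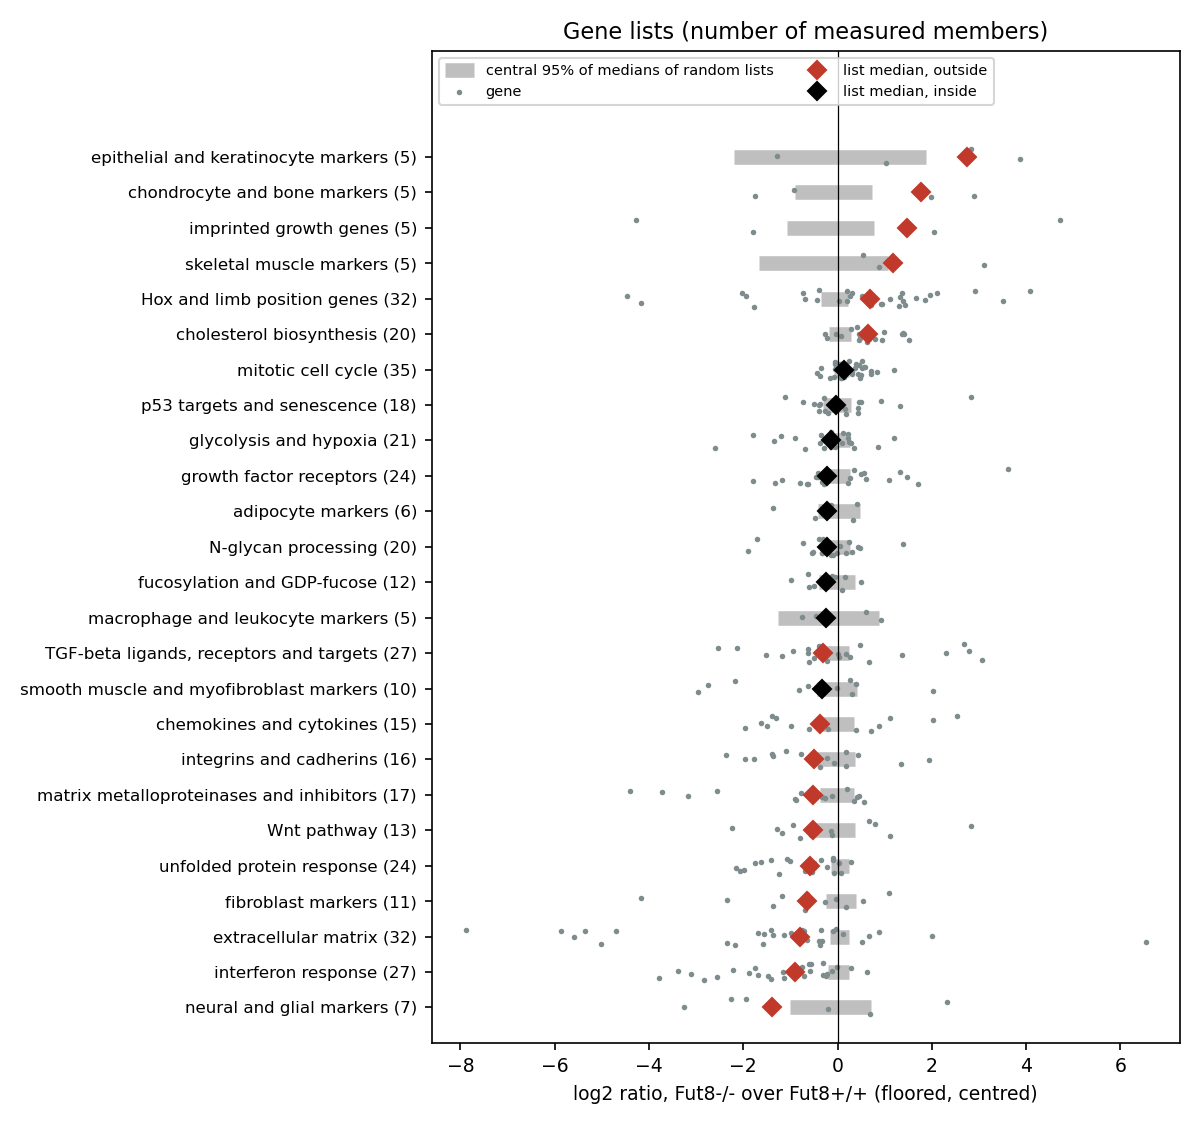
Each small point is a measured gene of the list named at the left (number measured in brackets), placed by its log2 ratio of Fut8-/- over Fut8+/+ on the x axis, with the list median as a diamond over a grey bar for the central 95% of medians of matched random lists. Red diamonds, 16 of 25, lie outside the bar, from -1.39 for neural markers to 2.74 for epithelial markers, and black ones inside it; the imprinted list turned to -1.68 without centring.

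In all, 16 of the 25 lists with a median lay outside the central 95% of random lists, 6 above and 10 below. By chance 1.25 would be expected outside if members of a list varied as independently as randomly drawn genes. Genes of one list or one chromosome can vary together, so 1.25 is too low a yardstick. Lists share genes, and the percentiles describe this pair of arrays. A difference between any pair of cultures would show in the same way, so none of these values is a test of genotype.

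The cultures also differed in sex-linked transcripts. The Y-linked genes Eif2s3y, Kdm5d and Uty were higher on the Fut8-/- array, where Eif2s3y had a signal of 2845 against 7.06, and Xist was lower. The remaining measured gene of chromosome Y, Orly, was dim on both arrays (28.8 and 34.2) and within 2-fold. Grouped by chromosome, a grouping chosen after the values were seen, genes shifted together over long stretches. The 377 measured genes of chromosome 13 had a median log2 ratio of 0.56, with 73 at least 2-fold higher and 9 at least 2-fold lower. On chromosome 12, which carries Fut8 and Fbln5, the median of 361 genes was -0.38 (8 higher, 51 lower), and on chromosome 7 the median of 714 genes was -0.32 (11 higher, 93 lower). Pitx1, Ogn, Omd, Tgfbi, Dsp, Idi1 and Nid1 lie on chromosome 13, Nid1 being the member with a lower signal. When each chromosome was divided into 10 consecutive segments, all 10 lay above the median of all genes on chromosomes 13 and 16 and all 10 below it on chromosomes 7 and 12. In total 16 of 20 chromosomes had a median outside the central 95% of random gene sets; neighbouring genes are not independent. The X chromosome was inside (0.02). Without chromosomes 7, 12, 13, X and Y, 499 genes were higher and 667 lower.

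**Figure D3:**
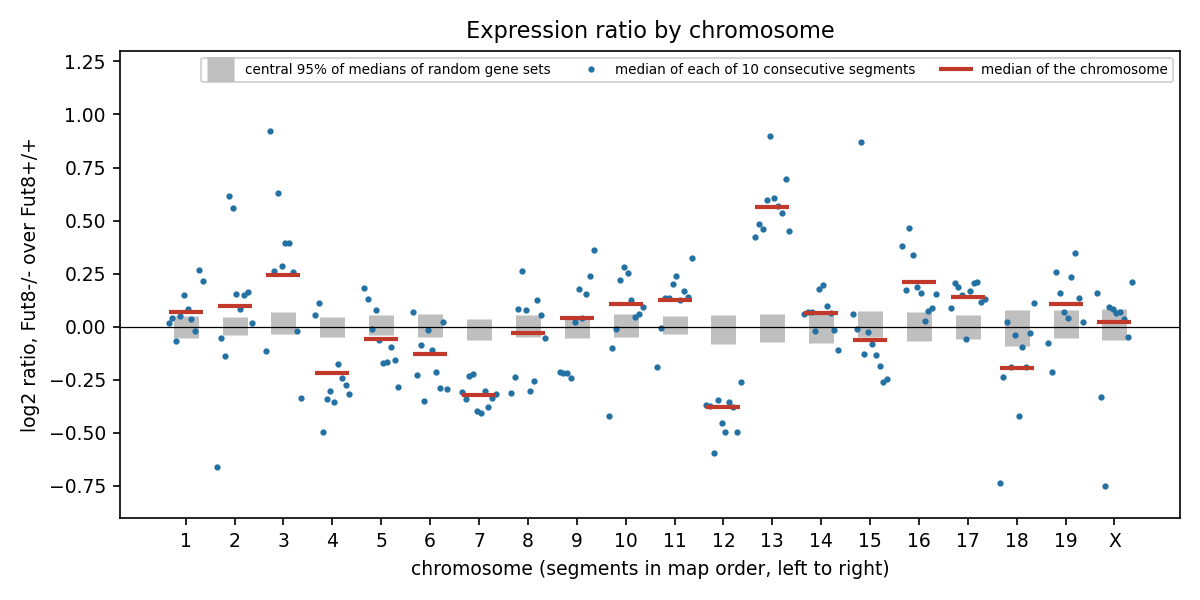
Red bars give the median log2 ratio of Fut8-/- over Fut8+/+ for the measured genes of each chromosome, blue points the medians of 10 consecutive segments in map order, and grey bars the central 95% of medians of random gene sets. All 10 segments of chromosome 13 (median 0.56) lie above the median of all genes, and all 10 of chromosomes 12 (-0.38) and 7 (-0.32) below it.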

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

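The filters at the 75th and 90th percentile and both settings on chromosomes were chosen only after the data were seen. Counts moved most with the filter on dim genes: 332 genes higher and 448 lower at the 75th percentile, 141 and 147 at the 90th, by construction, since fewer genes enter. Lists outside the random range numbered 9 at the 75th percentile, 6 at the 90th and 9 without a filter, against 16. The Fut8 level, as a log2 ratio against -3.81, was -2.29 with a floor at the 60th percentile and -2.81 with a pseudocount of 16, both of which raise the low Fut8-/- value, and 0 as the median over 3 probe sets, 2 of which were at the floor. The imprinted list's median of 1.47 turned to -1.68 without centring, because Igf2 and Phlda2, both lower, then passed the signal filter and made 7 members of 5, and to -0.088 without a filter, which lets all dim members in. The matrix, interferon, unfolded protein, cholesterol and fibroblast lists stayed outside under all 13 alternatives and the Hox list under all 12 that gave it a value, and so did the antioxidant list under all 13. In the other direction, the median of glycolysis and hypoxia was outside at -0.28 without chromosomes 7, 12, 13, X and Y, and that of smooth muscle and myofibroblast markers at -0.43 with each chromosome centred. Quantile normalization gave 661 higher and 791 lower, loess 623 and 835. Of single named genes, 1685 comparisons stayed within the spread between probe sets and 208 moved further; of list medians, 255 stayed, 80 moved and 2 reversed. No paired analysis was possible because each genotype has 1 array; for the same reason no array could be left out and no other split of the arrays made. Signal over background limits the lower end: 102 of the higher and 154 of the lower genes are bounds. In simulated data 370 of 17993 unchanged genes, including those too dim to be called, passed 2-fold.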

Other observations

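The tests of the array labels, of the sex of the cultures, of a lower share of fibroblasts and of RNA degradation were chosen only after their results were seen, and the 4 gene lists described here and the grouping by chromosome were chosen after the main results.

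Targets of the antioxidant regulator Nrf2 were higher in Fut8-/- as a group. Of 20 measured targets, 6 were at least 2-fold higher (4 without centring), 1 was at least 2-fold lower and 13 lay between, and the list median of 0.62 was above all 10000 random lists. The glutathione transferase genes Gstm1 (9.84-fold, from 227 to 1916) and Gstt1 (4.84-fold) had the largest ratios among the higher ones. The quinone reductase gene Nqo1 was 2.52-fold higher, and Gclc and Gclm, which encode both subunits of the enzyme that starts glutathione synthesis, were 2.19-fold and 2.17-fold higher, both below 2-fold without centring. The cystine transporter gene Slc7a11, which also belongs to the amino acid stress response, was at least 7.77-fold lower.

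Lysosomal enzymes were slightly lower, with a median of -0.32 over 28 measured genes (percentile 0.03 of random lists), and inside the random range at -0.09 without chromosomes 7, 12, 13, X and Y. Of these, 4 were at least 2-fold lower (6 without centring), the beta-glucuronidase gene Gusb by 4.57-fold, and 1, Acp2, was at least 2-fold higher. Genes of the DNA methylation machinery lay close together on both arrays: all 10 measured lay within 2-fold, and their median of -0.052 was inside the random range (percentile 38.03). Of the methylation-sensitive germline genes only 2 were measured, Dppa4 (-3.46) and Brdt (1.15, not measured without centring), too few for a median.

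Genes of whole chromosomes shifted together, with a median of 0.56, or 1.48-fold, on chromosome 13. A few strongly changed genes are unlikely to be the whole cause, since the lower quartile of the chromosome was itself 0.25. Without genes at least 2-fold apart the median was 0.45, above all random sets, an outcome that so high a quartile fixed in advance. After loess on the mean signal the median was 0.57, which argues against scaling that depends on signal. The random sets were already matched on mean signal, so loess could add little. For chromosome 12, leaving out Fut8 and its 20 nearest measured genes left a median of -0.38 over 340 genes, so those genes alone do not account for that shift. Removing so few genes could hardly move the median, and a longer passenger segment around the targeted locus was not tested separately. However, the segment medians of chromosome 12 ran from -0.60 to -0.26, with -0.37 and -0.26 at its ends. This argues against a passenger segment confined to part of the chromosome as the whole cause. A different copy number of chromosome 13 in one culture remains a candidate explanation: all 10 segments lay above the median of all genes, and both quartiles shifted by about as much as the median (0.63 and 0.53). The same holds for chromosomes 7 and 12, where all 10 segments lay below it. Their quartiles shifted by -0.23 and -0.37 on chromosome 7 and by -0.30 and -0.46 on chromosome 12. All 10 segments of chromosome 16 lay above it, with a smaller chromosome median of 0.21. DNA copy number was not measured, and shifts of part of a chromosome, such as segment medians of 0.92 on chromosome 3 and -0.75 on X, were not tested further.

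Of 4 measured Y-linked genes 3 were at least 2-fold higher in Fut8-/-, and Xist was 37.2-fold lower. A swap of the array labels is unlikely, because Fut8 itself had a log2 ratio of -3.81, a value that bears on the labels only if its probe set reads the deleted part. Cultures from embryos of different sex would need every Y-linked gene that the cells express to be higher in the same culture. Of the 4 measured, 3 were. Those 3, Eif2s3y, Kdm5d and Uty, were below the floor on the Fut8+/+ array. Their Fut8-/- signals were 2845, 655 and 413, while Xist went from 656 to 15.2, and these values go with a difference in sex. Orly, with a log2 ratio of 0.47, was within 2-fold but dim on both arrays (28.8 and 34.2, below the measured limit as deposited). So dim a gene cannot decide the question. The labels do not give the sex of the embryos. Xist and the 3 brighter Y-linked genes argue against cultures of the same sex. Effects of a difference in sex could not be separated from those of genotype in this pair. Of 328 measured genes on X or Y, 27 were at least 2-fold higher and 40 at least 2-fold lower, against 591 and 820 of 9836 on other chromosomes. Effects of sex on genes of those other chromosomes were not tested.

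Matrix and fibroblast genes were lower in Fut8-/-, Lox by at least 237-fold. A smaller share of fibroblasts among other cells would lower all their markers alike only if the other cells lacked them. That was not tested. Prrx1 (-4.16, a bound), Fbln2 (-2.34), Col1a1 (-1.37), Pdgfra (-1.17), Twist1 (-0.70) and Ddr2 (-0.65) were lower. However, 5 abundant fibroblast markers were not lower by more than the spread between probe sets. They were Col1a2 (-0.04, a Col1a2 log2 ratio of -0.26 without centring), Vim (0.17, but -0.05 without centring), S100a4 (0.54), P4hb (-0.27) and Pdgfrb (1.09). Without centring the P4hb log2 ratio was -0.49, past that spread, which leaves 4. Of 5 measured epithelial and keratinocyte markers, 4 were at least 2-fold higher and 1 at least 2-fold lower. The values argue against an even fall of all fibroblast markers, but a smaller share of fibroblasts stays open. RNA degradation on one array is unlikely, as the 3-prime to 5-prime ratios differed by at most 1.11-fold between arrays. With each chromosome centred the matrix median was -1.01, below all random lists. This argues against even shifts of whole chromosomes as the cause of the lower matrix list. A change that follows from the loss of Fut8 remains open and untested. So does a difference between independently derived or long-passaged cultures, in sex, position of origin, mix of cells or chromosome content other than such even shifts. Further Fut8+/+ and Fut8-/- cultures would be needed to separate them.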
